A study of Homo sapiens with 4 samples.

How the data were processed

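Gene expression was measured in HT1080 p21-9 cells, a human fibrosarcoma line carrying the cell cycle inhibitor p21 (gene CDKN1A) under a promoter that IPTG switches on. Per the labels' protocols, cells were grown in 10% serum and held for 72 h in medium with the DMSO carrier alone, with 5 µM Senexin A, an inhibitor of the Mediator kinases CDK8 and CDK19, with 50 µM IPTG, or with both. RNA was accepted at an integrity number of at least 9.0, per the labels' protocols. Each of the 4 cultures was hybridised to 1 Affymetrix human exon array. With 1 array per group there was no replicate check, and no p-value, standard error or count of significant genes was computed, since with these 4 arrays that would assume the absence of an interaction.

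The deposited intensity table held 22011 gene-level probes (transcript clusters) on a linear scale. Per the submitters' processing notes, these intensities came from Affymetrix Expression Console with RMA summarisation, with no version stated. The authors' second table held log2 fold changes of 17881 probes against the untreated array, made with GeneSpring GX, per the file headers. The design fixed beforehand assumed log2 values. The deposited intensities ran from 1.80 to 18678, so log2 was taken here, with no pseudocount.

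Probes were named from the platform table through Entrez IDs, and symbols were updated through the RefSeq gene table. Of the probes, 14432 carried 1 gene symbol, of which 14404 matched by Entrez ID, 2408 carried several symbols and 5171 carried none. Probes of the last 2 kinds were not counted as genes. That left out several well known genes of the fixed lists, which were not analysed here. The array's genome build was not named, so no coordinates are given. For the 197 genes with over 1 probe, the probe with the highest mean over the arrays was used. A gene was counted where its highest value over the 4 arrays lay above the pooled median of all probe values (log2 7.33, intensity 161), which gave 8395 of 14232 named genes. For arrays, their number limits the precision.

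All differences are log2 differences between arrays. The 6 comparisons were IPTG minus untreated, Senexin A minus untreated, IPTG with Senexin A minus Senexin A, IPTG with Senexin A minus IPTG, the combined treatment minus untreated, and the interaction, which is the IPTG effect with Senexin A minus the IPTG effect without it. The IPTG effects without and with Senexin A share no array, and neither do the Senexin A effects without and with IPTG. Genes were counted at a fixed size of 2-fold, a log2 difference of 1, in either direction. The verbs rose and fell are used only of genes past that size. The retained response was the share of genes past 2-fold with IPTG alone that were also past 2-fold the same way when Senexin A was present, with an exact Clopper-Pearson 95% interval, and the median ratio of their log2 effects. These intervals treat genes as independent, which they are not.

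For each list of genes, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile describes these arrays only. After the results were seen, the lists were also placed among the genes above the floor in both IPTG arrays. A list was said to stand above or below matched lists outside the central 95% of their medians. Intervals of medians are 95% order-statistic intervals. The 26 lists with 543 entries were fixed before the data were examined, as were the comparisons, the size threshold, the floor and the rule for named genes. They covered mitosis and cytokinesis, DNA replication, DNA repair and chromatin, replication-dependent histones, cyclins with CDKs and CDK inhibitors, the Mediator kinase module, p53 targets other than CDKN1A, extracellular matrix, extracellular proteases and inhibitors, NF-kB and inflammatory genes, secreted growth factors, lysosome, type I interferon response, serum and immediate early genes, TGF-beta and SMAD targets, Wnt targets, cholesterol and fatty acid synthesis, hypoxia and glycolysis, the unfolded protein and integrated stress response, AhR targets, NRF2 targets, cytoplasmic ribosomal proteins, reference genes, and markers of epithelial cells, leukocytes and endothelial cells. Of these, 25 had at least 3 counted members.

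Named genes were CDKN1A and the Mediator kinase module genes CDK8, CDK19, CCNC, MED12 and MED13, the 10 highest and 10 lowest counted genes, leaving out provisional symbols and small RNA and olfactory receptor genes, in 4 of the comparisons (IPTG minus untreated, Senexin A minus untreated, IPTG with Senexin A minus IPTG, and the interaction), and up to 4 members of each list with the largest absolute difference. The rule gave 243 genes. Genes named outside it are said to be chosen after their values were seen.

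The alternatives fixed beforehand were size thresholds of 1.5-fold and 3-fold, no floor, a floor on the mean, a floor at the pooled 75th percentile, quantile normalization, cyclic loess (span 0.7, 3 iterations), centring on the reference genes, the mean of a gene's probes, the authors' fold-change table, and the exchange of the selecting and the tested IPTG effect. After the data were seen, 4 alternatives for the retained response were added. These were the median of the counted genes removed, the same in the authors' table, the same after cyclic loess, and the authors' table with a running median over brightness (1001 probes) removed.

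The spread between probes of the same gene stood in for noise: over 76 genes and 152 probes its SD was 0.507 for IPTG minus untreated and 0.275 for Senexin A minus untreated, on the log2 scale. The counting code was tested on simulated data made for IPTG minus untreated over 8395 genes, with 200 changed genes and noise of SD 0.212 per array, taken from the scatter of the interaction over the counted genes. With 1 array per group this noise could not be measured, and the spread between probes with IPTG was larger. The code passed 2-fold for 6% of 50 genes changed 1.5-fold, 50.0% of 50 changed 2-fold, and 100% of those changed 3-fold and of those changed 4-fold, and for 8 of 8195 unchanged genes. Normalization used limma 3.58.1 in R 4.3.3. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.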

Results

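The data were 4 expression arrays of HT1080 p21-9 cells, 1 for each of 4 treatments held for 72 h: untreated, Senexin A (5 µM), IPTG (50 µM), and IPTG with Senexin A. The median probe intensity was 174.4 in the untreated array, 166 with Senexin A, 149 with IPTG and 159 with both. Among the 8395 counted genes the median was 422, 367, 294 and 333 in the same order. No treatment had a replicate array, so every value below compares single arrays.

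According to the series title, the design asks how an inhibitor of CDK8 and CDK19 alters the expression changes that p21 brings about. CDKN1A (probe 2905169), the gene IPTG was meant to induce, had an intensity of 491 in the untreated array, 549 with Senexin A, 681 with IPTG and 671 with both. Its log2 difference was 0.47 for IPTG without Senexin A and 0.29 with it, against an SD of 0.507 and 0.301 between probes of a gene. Relative to the counted genes as a whole the IPTG difference of CDKN1A was 0.87, and it was 1.02 after quantile normalization and 0.98 after cyclic loess. In the authors' table the IPTG effect was 0.74 without Senexin A and 0.20 with it. Both IPTG arrays lay above both arrays without IPTG for this gene in the deposited intensities. Whether this probe set measures the introduced p21 as well as the cell's own is not known, so these values are no measure of the degree of induction.

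The targets of the inhibitor were measured as well. CDK8 (probe 3482498) had intensities of 751 untreated, 726 with Senexin A, 483 with IPTG and 611 with both, and CDK19 had 196, 162, 179 and 239.6. CCNC, the cyclin partner of both kinases, fell with IPTG by 1.41, and its difference with Senexin A alone was -0.58. MED12 and MED13, the subunits that hold the kinases in Mediator, had IPTG differences of -0.15 and -0.40. The median of the 7 genes of the Mediator kinase module with IPTG, -0.40, lay at percentile 52.0 of matched lists. In the authors' table the IPTG differences of CDK8, CDK19, CCNC, MED12 and MED13 were -0.43, 0.63, -1.22, 0.10 and -0.24. The direction for CDK19 and MED12 thus turned with the source of the values.

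IPTG alone was accompanied by far lower levels of the genes of dividing cells. Of the 31 counted genes of mitosis and cytokinesis, 30 fell at least 2-fold, with a median of -3.43 (95% interval -3.71 to -3.05) against -0.46 in matched lists. CDC20, the activator of the anaphase-promoting complex, fell 17.4-fold, to an intensity of 192. KIF11 (probe 3258168), the motor that separates the spindle poles, went from 388 to 20.6, and CDK1, the kinase that drives entry into mitosis, from 357 to 24.7. SGO1, which protects centromere cohesion and was named as 1 of the 10 lowest genes outside the list, went from 651 to 28.5. With IPTG 23 of the 31 listed genes lay under the floor of 161, where values near background make the size of a fall uncertain, and this holds for 625 of all 1565 genes that fell. The median of the list lay at the bottom of the 10000 matched lists in 9 of 9 settings.

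DNA replication, DNA repair and histone genes fell with them. Of 28 DNA replication genes 25 fell, with a median of -2.36 (-2.92 to -1.84). RRM2, a subunit of ribonucleotide reductase, went from 2575 to 107 in intensity, MCM10 from 782 to 60.6, and CDC6, a loader of the replicative helicase, from 1121 to 94.6. All 15 counted genes of DNA repair and chromatin fell, with a median of -2.69 (-3.20 to -1.90), among them FANCI, from 503 to 48.8 in intensity, and BLM, from 369 to 40.1. With IPTG 14 of these 15 genes and 16 of the 28 DNA replication genes lay under the floor, so the sizes of their falls are uncertain too, and the excess of the DNA repair and chromatin list over matched lists, -2.29, was -1.41 with the floor at the pooled 75th percentile. The 9 replication-dependent histone genes all fell, with a median of -3.27 (-4.69 to -1.84), and H3C1, named as 1 of the 10 lowest genes, went from 1544 to 42.8. The histone values are uncertain gene by gene, since these genes are near-identical copies. Among cyclins, CDKs and CDK inhibitors, 3 of 9 fell, CDK2 by 2.27, CDKN1B by 1.09 and CCND3 by 1.02, and the list's median of -0.32 lay at percentile 50.7.

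The genes that rose with IPTG were led by secreted and matrix products. MFAP5, a component of microfibrils, went from an intensity of 35.6 to 593, FN1 (probe 2598261), which encodes fibronectin, from 157 to 1659.9, MMP7 from 69.8 to 566 and MMP9, also a matrix metalloproteinase, from 481 to 2823. The untreated values of MFAP5, FN1 and MMP7 lay under the floor of 161, so the sizes of these rises are uncertain. Of all 56 genes that rose, 16 lay under the floor in 1 of the arrays compared and 1 in both. Complement C3 rose 4.15-fold, and SLFN5, ACSF2, ABCC3, TXNIP and IFIT2 by 1.91, 1.89, 1.82, 1.70 and 1.63 on the log2 scale. Of 23 extracellular matrix genes 4 rose (FN1, COL6A1, FBN1 and CCN2) and none fell, with a median of 0.22 (0.03 to 0.57) against -0.40 in matched lists. Of 11 extracellular proteases and inhibitors 3 rose, MMP9, MMP2 by 1.10 and the lysosomal protease CTSB by 1.02, and the median was 0.75 (-0.67 to 1.10) against -0.37.

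Lysosomal genes stood above matched lists too. Their median was 0.31 (0.04 to 0.73) against -0.42, and 3 of 22 rose, the acid glucosidase GAA by 1.29, the granulin precursor GRN by 1.23, and CTSB, which the protease list also holds, while GUSB fell by 1.40. The type I interferon list had a median of 0.42 against -0.27 (percentile 99.93), but 1 of 12 genes rose (IFIT2) and 1 fell (XAF1, by 1.45). The NF-kB and inflammatory list had 4 of 20 genes that rose, C3, IL32 by 1.42, the chemokine CCL2 by 1.29 and TRAF1 by 1.02, and 3 that fell, the cytokine IL1B by 1.84, NFKB1 by 1.43 and CXCL8 by 1.21. Its median lay 0.39 above that of matched lists (percentile 99.54, and 95.1 at the lowest over the settings). TGF-beta and SMAD targets had a median of 0.23 against -0.41 (percentile 99.94), with CCN2 risen by 1.08 and ID1 fallen by 1.03.

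Most other lists lay within the range of matched lists with IPTG, though some members moved. Of 19 serum and immediate early genes 6 fell, including the transcription factor MYC by 1.74 and JUN by 1.33 (median -0.57, percentile 20.3). Of 17 cholesterol and fatty acid synthesis genes 3 fell, HMGCS1 by 1.87, INSIG1 by 1.74 and SQLE by 1.40 (median -0.52, percentile 26.3). In the unfolded protein and integrated stress response the asparagine synthetase ASNS fell by 2.32 and CHAC1 by 1.21 (median -0.60, percentile 24.3), and among NRF2 targets the cystine transporter SLC7A11 fell by 2.89 (median -0.48, percentile 30.4). Among p53 targets other than CDKN1A, TP53INP1 rose by 1.14 and BAX fell by 1.26 (median -0.27, percentile 83.1). The medians of the remaining lists were -0.11 for hypoxia and glycolysis (percentile 93.7), -0.51 for 4 Wnt targets (31.0), 0.38 for 3 AhR targets (92.9), -0.02 for 7 cytoplasmic ribosomal proteins (89.5) and -0.07 for 13 secreted growth factors (97.4, and outside the central 95% in 5 of 9 settings). The reference genes, often taken as stable, lay below matched lists (median -0.80 against -0.37, percentile 1.80), with HPRT1 down by 1.76. This held in 7 of 9 settings, and the highest percentile was 13.7. Few markers of other cell types were above the floor: 0 of 12 leukocyte markers were counted, 5 of 13 epithelial markers had a median of 0.33, above matched lists (percentile 97.9, and outside the central 95% in 4 of 8 settings), and 3 of 10 endothelial markers had one of 0.15 (percentile 84.2).

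In all, 56 genes rose and 1565 fell past 2-fold with IPTG alone in the deposited intensities. This split moved with the scaling, and the median of all counted genes was itself -0.40. That shift depended on the floor: with no floor the median over 14232 named genes was -0.05. The split there was 114 to 1719, and 146 to 1517 with that median removed. The splits that follow are of genes above the floor. The split was 307 to 645 with the median of -0.40 removed, 295 to 650 after quantile normalization, 216 to 767 after cyclic loess, 164 to 863 with the reference genes centred, and 678 to 647 in the authors' fold-change table, where the median was -0.05. The list medians above are set against matched lists for this reason. The members said to have risen or fallen were counted on differences that keep the shift of -0.40, so those counts follow the scaling too. Of the 678 genes that rose in the authors' table, 596 lay in the dimmer part of the counted genes, and with the probes sorted by brightness into 10 bins, its IPTG column ran from 0.90 in bin 4 to -0.38 in bin 10, the brightest.

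**Figure D1:**
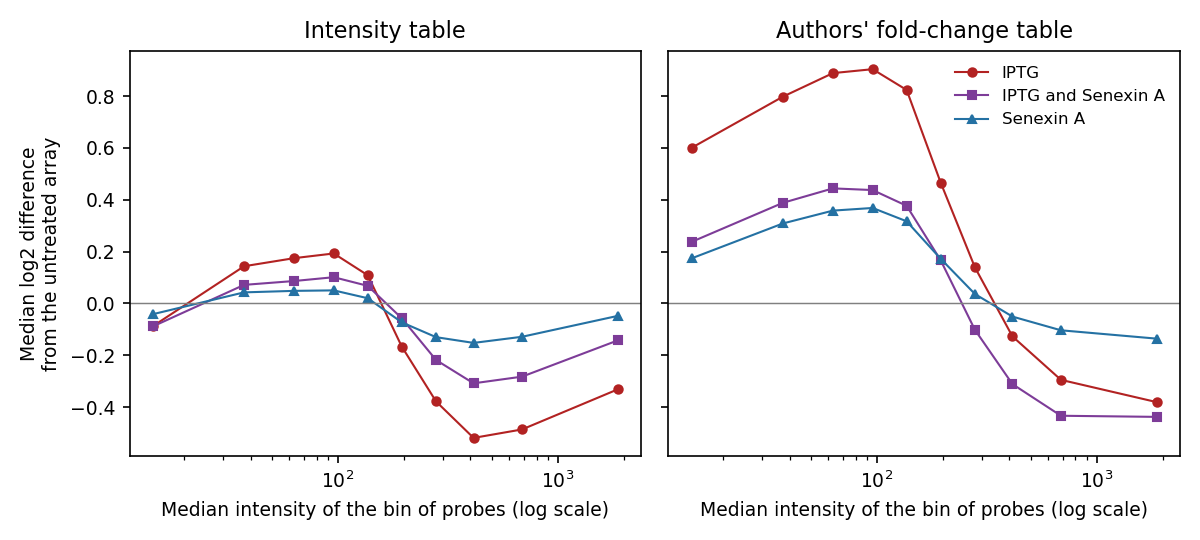
Median log2 difference from the untreated array (vertical axis) in each of 10 bins of the probes by brightness, plotted at the median intensity of the bin on a log scale, for the IPTG, IPTG with Senexin A and Senexin A arrays in the deposited intensity table and in the authors' fold-change table. With IPTG the intensity table runs from 0.19 in bin 4 to -0.52 in bin 8, and the authors' table from 0.90 in bin 4 to -0.38 in bin 10.

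With Senexin A present, most genes of the same cell cycle lists fell with IPTG, and the matrix, protease and lysosomal lists stood above matched lists. All 31 mitosis and cytokinesis genes fell, with a median of -2.61 (-2.83 to -2.38), as did 25 of 28 DNA replication genes (median -1.78), 14 of 15 DNA repair and chromatin genes (-2.25) and 9 of 9 histone genes (-2.36). FN1 rose 14.1-fold, and from values under the floor MFAP5 went from 57.2 to 987, MMP7 from 114 to 1328 and the protease inhibitor SERPINE2 from 145 to 611. The extracellular matrix list had 6 of 23 genes that rose (median 0.42 against -0.09), proteases and inhibitors 5 of 11 (0.85 against -0.08), and lysosome 5 of 22 (0.58 against -0.10), each at percentile 100 of matched lists. TGF-beta and SMAD targets had a median of 0.43 (percentile 100), secreted growth factors 0.18 (percentile 99.1), the type I interferon list 0.25 (percentile 99.8) and the NF-kB and inflammatory list 0.04 (percentile 92.7).

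Across the counted genes the IPTG effects without and with Senexin A, which share no array, had a Pearson r of 0.80 and a Spearman rho of 0.72. That is a correlation across genes, which are not independent replicates. With the medians of all counted genes removed, 332 genes were at least 1.5-fold higher and 637 at least 1.5-fold lower in both, where independent lists would share 98.4 and 144, and 2 moved in opposite directions, where independent lists would give 242. Past 2-fold, 114 genes rose and 339 fell with IPTG in the presence of Senexin A, and the split was 153 to 274 after quantile normalization and 167 to 261 with the reference genes centred.

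Of the 56 genes that rose with IPTG alone, 40 also rose past 2-fold with Senexin A present (71.4%, 57.8 to 82.7), with a median ratio of log2 effects of 0.98. Of the 1565 that fell, 333 also fell past 2-fold (21.3%, 19.3 to 23.4), with a median ratio of 0.42. Selected on the arrays with Senexin A and tested without it, the shares were 40 of 114 (35.1%) and 333 of 339 (98.2%). Genes selected on 1 pair of arrays tend to shrink toward 0 on any other pair, so these shares do not measure a loss due to Senexin A. The fixed size was also applied to effects with unlike medians, -0.40 without and -0.08 with Senexin A. With those medians removed, an alternative added after the data were seen, the shares were 29.6% for genes that rose and 42.8% for genes that fell. These shares followed the scaling: for the genes that rose, 33.2% after quantile normalization, 39.4% after cyclic loess and 8.41% (57 of 678) in the authors' table, and for those that fell, 39.4%, 36.5% and 46.7%.

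**Figure D2:**
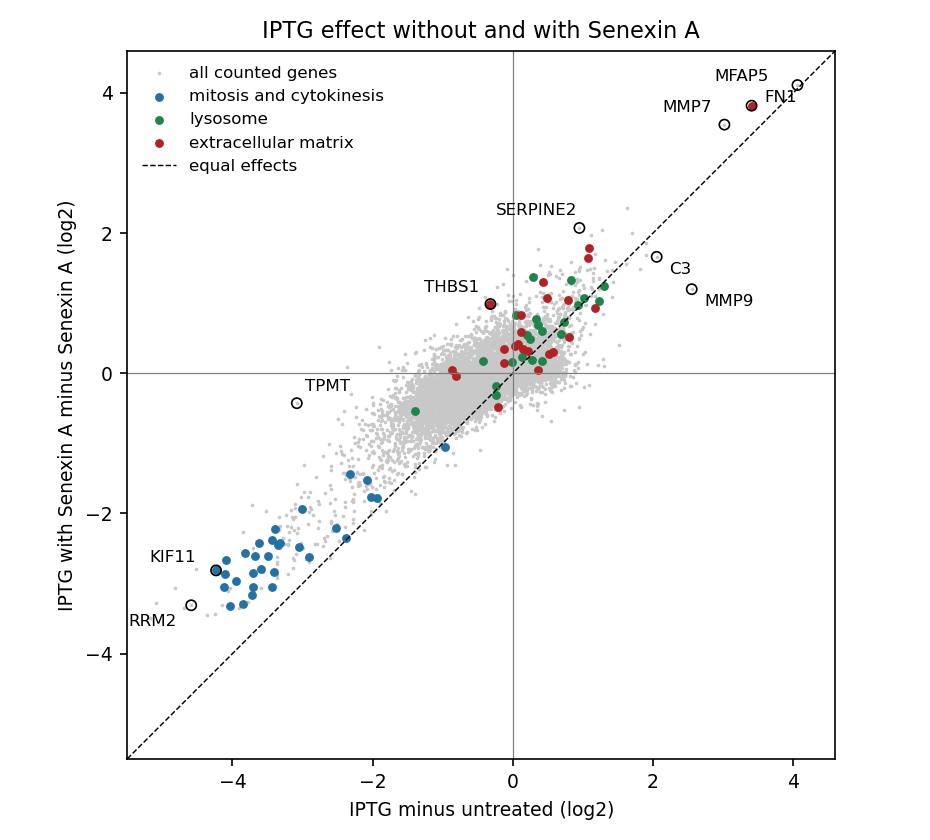
Log2 difference of IPTG minus untreated (horizontal axis) against IPTG with Senexin A minus Senexin A (vertical axis), 1 grey point per counted gene, with the mitosis and cytokinesis, lysosome and extracellular matrix lists in colour, 10 named genes ringed and a dashed line of equal effects. The 31 mitosis and cytokinesis genes lie between -4.23 and -0.97 without Senexin A and between -3.32 and -1.06 with it, and FN1 lies at 3.41 and 3.82.

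Senexin A alone moved few genes past 2-fold. The genes that rose were HHIP, a hedgehog-binding protein (129 to 307 in intensity), AMIGO2 by 1.19, the integrin subunit ITGB3 by 1.16, INHBA (probe 3047581), which encodes the activin A subunit, by 1.14, the TGF-beta target PMEPA1 by 1.08, and EDN1, the endothelin precursor, which went from 101.7 to 203 in intensity. Among those that fell were PLEKHA3 by 1.41, TPMT by 1.31, TMEM71 by 1.20, the pentraxin PTX3 by 1.18 and SKP1 by 1.13. TGF-beta and SMAD targets stood above matched lists (median 0.34 against -0.11, percentile 100), with 1 of 13 past 2-fold (PMEPA1) and TPM1 at 0.83. So did the extracellular matrix (0.19 against -0.11, percentile 100), where none of 23 genes passed 2-fold and the collagens COL4A1 and COL4A2 stood at 0.58 and 0.49. CCN2 and TGFBI belong to both lists.

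The NF-kB and inflammatory list was also above matched lists with Senexin A alone (0.05 against -0.12, percentile 99.94), with none of 20 genes past 2-fold. Mitosis and cytokinesis lay below them (-0.34 against -0.15, percentile 0.17), with none of 31 past 2-fold, and this turned to 0.03 above matched lists with the floor at the pooled 75th percentile. Replication-dependent histones (-0.36, percentile 1.72), with H2BC3 fallen by 1.30, and reference genes (-0.29, percentile 1.19) lay below as well. The counts past 2-fold were 6 higher and 21 lower in the deposited intensities, 9 to 8 with the median of the counted genes (-0.12) removed, 6 to 4 after quantile normalization, 10 to 10 with the reference genes centred and 10 to 5 in the authors' table.

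Added to IPTG, Senexin A was accompanied by higher levels of matrix genes and TGF-beta targets. INHBA went from 462 with IPTG to 1726 with both, THBS1, which encodes thrombospondin 1, from 488 to 1763, HHIP from 218 to 743 and the growth factor TGFB2 from 374 to 1202. SLC29A1 rose by 1.61, and CUL4B and TMEM45A by 1.54 each. The extracellular matrix list had a median of 0.59 (0.20 to 0.88) against 0.19 in matched lists (percentile 100, and 96.5 at the lowest over the settings), with 12 of 23 genes at least 1.5-fold higher. TGF-beta and SMAD targets had a median of 0.48 (0.13 to 0.74) against 0.18 (percentile 99.96, lowest 97.35), with ID3 risen by 1.20 and CCN2 by 1.08. Secreted growth factors stood at 0.38 against 0.18 (percentile 98.6, lowest 69.9, outside the central 95% in 5 of 9 settings). In the authors' table their median was -0.01, where that of all counted genes was -0.18. Of these 13 genes 2 rose, INHBA and TGFB2.

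Mitosis and cytokinesis genes stood above matched lists with both compounds against IPTG alone, at a level still far below untreated cells. Their median was 0.48 (0.36 to 0.61) against 0.19 in matched lists (percentile 100, lowest 99.1). DNA replication genes stood at 0.42 against 0.18 (percentile 99.99). In the authors' table the medians were -0.04 against -0.19 and -0.02 against -0.20, so there the lists were above matched lists without being higher. Under the floor in both IPTG arrays were 19 of the 31 and 14 of the 28 genes. Among the 8 and 11 genes above it in both arrays the medians, 0.27 and 0.33, lay at percentile 69.3 and 91.7, within the range of matched lists. The median of mitosis and cytokinesis genes against untreated cells remained at -2.95 with both compounds.

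The inflammatory lists lay on the other side. The type I interferon list had a median of -0.18 against 0.13 in matched lists (percentile 0.05, below 2.5 in 8 of 8 settings), with none of 12 genes past 2-fold. The NF-kB and inflammatory list had a median of 0.01 against 0.17 (percentile 0.50, below 2.5 in 7 of 9 settings), and its members went both ways: CCL2 stood at -0.59 and TRAF1 at -0.27, while IL1B and IL6 rose by 1.17 and 1.15. Epithelial markers stood at -0.15 (percentile 0.79, below 2.5 in 6 of 8 settings) with 5 genes. Of single genes, the carboxypeptidase subunit CPN1 fell by 1.06 and TNFRSF9, a receptor of the TNF family, by 1.05. With Senexin A added to IPTG, 68 genes rose and 3 fell past 2-fold in the deposited intensities (6 and 1 of them under the floor in both arrays), where the median of the counted genes was 0.17. In the authors' table it was -0.18 and 7 rose and 7 fell.

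The interaction compares the IPTG effect with Senexin A against that without it. It stood above matched lists for 3 of the 4 cell cycle lists: the median was 0.87 (0.57 to 1.05) for mitosis and cytokinesis against 0.35 in matched lists (percentile 100, lowest 97.9), with 10 of 31 genes past 2-fold, 0.60 for DNA replication against 0.33 (percentile 99.48, lowest 93.2) and 0.92 for histones against 0.34 (percentile 99.94). For DNA repair and chromatin it was 0.48 against 0.34 (percentile 77.6). The random lists were matched on brightness, not on the size of the IPTG effect. That effect was smaller with Senexin A over all counted genes (SD 0.52 against 0.73), which by itself can lift a list that fell far. Among genes above the floor in both IPTG arrays, the interaction of mitosis and cytokinesis (0.35, percentile 54.0) and of DNA replication (0.37, percentile 60.7) lay within the range of matched lists. For the 5 histone genes above that floor the interaction was 0.851 against 0.254 (percentile 99.93). The histone percentiles count near-identical copies as separate genes, which their probes may not be able to tell apart. In the combined treatment minus IPTG the 9 counted histone genes were not above matched lists (0.24 against 0.20, percentile 62.9). The 5 above the floor in both IPTG arrays were above them (0.653 against 0.185, percentile 99.87). Of 9 settings, 1 put the histones above matched lists there, the floor on the mean (6 genes, 0.445 against 0.181, percentile 99.01). With Senexin A alone the histones lay below matched lists in 9 of 9 settings. The interaction lay below matched lists for NF-kB and inflammatory genes (0.05 against 0.30, percentile 0.64, below 2.5 in 9 of 9 settings). There CCL2 had an IPTG difference of 1.29 without Senexin A and 0.10 with it, and an interaction of -1.19, while IL6, at -0.30 and 0.82, went the other way at 1.12. The type I interferon list (-0.12 against 0.24, percentile 1.98, below 2.5 in 5 of 8 settings) and the epithelial markers (-0.23, percentile 0.87, below 2.5 in 7 of 8) also lay below.

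The named gene with the lowest interaction after ALOX5AP (-1.42) was MMP9 (probe 3887210), whose IPTG difference was 2.55 without and 1.20 with Senexin A (interaction -1.35). The highest interactions among the named genes were those of TPMT (2.65), COX20 (2.45), PLEKHA3 (2.28), CEBPZ (2.01) and SKP1 (1.92), all of which fell with IPTG alone. TPMT and PLEKHA3 lay under the floor in both IPTG arrays. MYC fell by 1.74 with IPTG alone and stood at -0.44 with Senexin A present. In the deposited intensities the interaction passed 2-fold upward for 604 genes and downward for 13, with a median of 0.30 over the counted genes. The split was 144 to 65 with that median removed, 195 to 54 after quantile normalization, and 28 to 447 in the authors' table, whose median was -0.15, so the direction of the interaction over all genes turned with the source of the values.

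Against untreated cells, matrix genes stood higher with the combined treatment than with either compound alone. The extracellular matrix list had a median of 0.81 (0.38 to 1.22), 8 of 23 genes rose and none fell, with CCN2 4.45-fold and THBS1 2.90-fold higher and FN1 at 2834 against 157. ITGB3 stood 6.59-fold and TGFB2 4.69-fold above untreated cells, and HHIP at 743 against 129. The counts past 2-fold were 132 higher and 708 lower, 206 to 413 with the median of the counted genes (-0.22) removed, 214 to 374 after quantile normalization, 197 to 462 after cyclic loess and 217 to 390 with the reference genes centred.

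**Figure D3:**
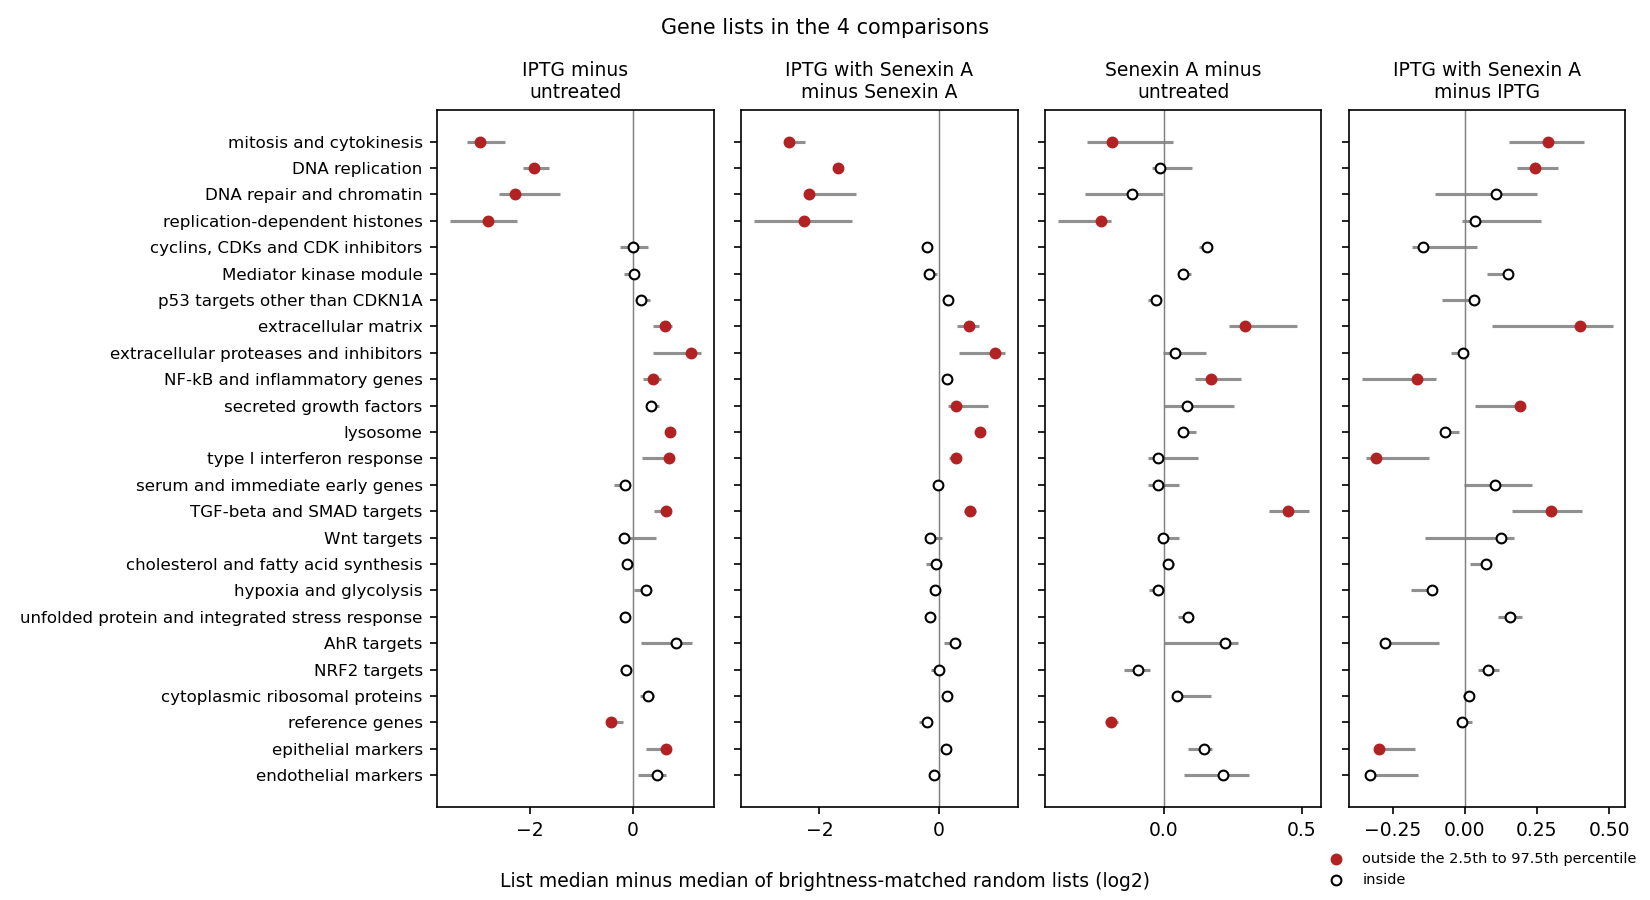
Median log2 difference of each of 25 gene lists minus the median of brightness-matched random lists (horizontal axis, log2), in 4 comparisons, each panel with its own scale. Points are the deposited intensities, red where the list lies outside the central 95% of 10000 random lists, and grey lines run from the lowest to the highest value over the settings; mitosis and cytokinesis lies at -2.97 with IPTG and TGF-beta and SMAD targets at 0.45 with Senexin A.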

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

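The tests of the patterns below were chosen after the results were seen, except the test of the brightness trend in the authors' table. The pattern of the table difference was itself restated after its values were known. Patterns on cell cycle genes and on TGF-beta targets were picked after the list medians were seen, from lists fixed before the data were examined.

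Opposite effects in the presence and absence of the other compound were listed for named genes past 1.5-fold both ways, a size set after the list medians were seen. With 1 array per group, none of these differences was tested. The Senexin A effect without and with IPTG was 0.67 and -0.68 for MMP9, -1.41 and 0.87 for PLEKHA3, and -1.31 and 1.35 for TPMT. It was -1.13 and 0.79 for SKP1, -1.11 and 1.34 for COX20, -0.93 and 0.90 for CEP15, and -0.69 and 1.13 for GPX8. It was 0.65 and -0.61 for LCN12, 0.60 and -0.59 for CCL2, and -0.63 and 0.80 for ANLN. In the effect with IPTG, PLEKHA3, TPMT and CEP15 lay under the floor in both arrays. The IPTG effect without and with Senexin A was -0.81 and 0.70 for DPH3. In the authors' table MMP9, TPMT, COX20, LCN12 and CCL2 were past 1.5-fold both ways too, and the others were not. The Senexin A effects there were -0.92 and 0.30 for PLEKHA3, -0.74 and 0.25 for SKP1, and -0.64 and 0.30 for CEP15. They were -0.41 and 0.52 for GPX8 and -0.68 and 0.32 for ANLN, and the IPTG effects of DPH3 were -0.23 and 0.57. At any size, opposite signs were seen for 160 of 243 named genes and 20 of 25 lists in the Senexin A effect, and for 50 genes and 5 lists in the IPTG effect. These counts say little, since the median Senexin A effect over all counted genes was itself -0.12 without and 0.17 with IPTG, and the named genes include those with the highest and lowest interaction. The 2 Senexin A effects share no array, and across the counted genes their r was -0.32.

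A signal was also present in data that no comparison used. Among 3898 probes above the floor with several gene symbols or none, 37 rose and 834 fell past 2-fold with IPTG alone. The share that fell, 95.8%, was close to the 96.5% of the counted genes, a share that follows the scaling, since with the median removed the counted genes split into 307 and 645.

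The first pattern was that the genes past 2-fold with IPTG differed between the deposited tables, 56 higher and 1565 lower in the intensities against 678 and 647 in the authors' table, with 54 and 634 in common. A brightness-dependent difference between arrays as the whole cause of the fall of mitosis and cytokinesis genes is excluded, since after cyclic loess their median was still -3.28 (-3.54 to -2.56). With a brightness trend removed from the authors' table, 240 genes rose, of which 34.6% (28.6 to 41.0) also rose with Senexin A, in place of 8.41%. This step had to take out many of the 678 whatever their cause, since 596 lay in the dimmer part. It also left 765 genes that fell, in place of 647, with 607 of the 765 in the dimmer part. The intensities after cyclic loess gave a similar split of 216 to 767, so the step does not show which table holds the trend. Scaling of the arrays as a source of the shift of all counted genes cannot be told apart, because the 0.345 by which that shift differed between the tables restates the difference in counts. Whether total RNA per cell changed with p21 stays open and untested, so counts over all genes may reflect scaling as much as expression.

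The second pattern was that cell cycle genes fell less with IPTG when Senexin A was present, which was seen against matched lists for mitosis and cytokinesis, DNA replication and histones but not for DNA repair and chromatin (percentile 77.6). Lists were matched on brightness, not on the size of the fall. IPTG effects over all counted genes were smaller with Senexin A (SD 0.52 against 0.73), which by itself can lift a list that fell far. The mitosis and cytokinesis median was -3.43 without and -2.61 with Senexin A. All genes that fell had a median ratio of log2 effects of 0.42, and of 0.62 with the medians removed. A smaller IPTG effect over all genes thus cannot be told apart from one particular to these lists. For histones the interaction lay at percentile 99.68 or higher in each of 4 scalings, and at 99.93 with the 5 genes above the floor in both IPTG arrays. These genes are near-identical copies, so their probes may not be separate measurements. The percentiles count each as separate and may be too extreme for that reason. Lists matched on brightness already take out an array-wide shift and most of a brightness trend. The repeat over scalings therefore adds little, and scaling was not tested independently. For mitosis and cytokinesis and for DNA replication the interaction lay at percentile 100 and at 99.3 or higher in these scalings. Those percentiles rest largely on genes under the floor, and with those left out the interaction lay at percentile 54.0 and 60.7, so scaling cannot be told apart for these 2 lists. Over these 2 lists as a whole the values argue against a lower starting level in the Senexin A array as the whole cause. Their medians in Senexin A minus untreated, -0.337 (-0.494 to -0.158, percentile 0.17) and -0.150 (-0.248 to -0.0478, percentile 39.9), lay above the -0.668 and -0.406 it needs to give the whole interaction. It is not excluded, since these intervals hold no spread between arrays and the needed values rest largely on genes under the floor with IPTG. Values near background cannot be told apart as the cause either: in IPTG with Senexin A minus IPTG the 8 and 11 genes above the floor lay at percentile 69.3 and 91.7, too few to decide, with medians of 0.27 (-0.10 to 0.83) and 0.33 (-0.11 to 0.71). For histones a lower starting level cannot be told apart, since the interval of their median with Senexin A alone, -0.359 (-0.811 to -0.169), holds the -0.705 it needs. The 5 histone genes above the floor in both IPTG arrays, too few for an interval, stood at -0.208 there (percentile 13.3, lowest member -0.615). In IPTG with Senexin A minus IPTG these 5 were above matched lists, at 0.653 against 0.185 (percentile 99.87), so the answer differs with the genes taken. A different degree of p21 induction in the IPTG cultures cannot be told apart, since CDKN1A differed by -0.0215 between them in the deposited intensities against an SD of 0.268 between probes of a gene, and by -0.316 in the authors' table, where the median of the counted genes was -0.184. Whether its probe set measures the introduced p21 is not known, and p21 protein was not analysed here. An opposition of Senexin A to the p21 effect on these genes is among the open explanations, untested.

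The third pattern was that TGF-beta and SMAD targets were higher with Senexin A. The list stood above matched lists in both pairs of arrays, without and with IPTG, which share no array, with a lower percentile of 99.96. The pattern was picked after both values were seen, so they cannot decide against a difference between single arrays. With IPTG present the list stood above matched lists in 8 of 9 settings and lay at 97.35, just within their range, with no floor, where genes near background enter the list. The lowest percentile in Senexin A minus untreated over 3 scalings was 100. Matching on brightness already takes out most of a scaling effect, so this repeat adds little and scaling was not tested independently. A higher level of TGF-beta target genes under Senexin A, of which 1 of 13 passed 2-fold, may be biological, a hypothesis found and tested on the same 4 arrays. Differences between single cultures that have nothing to do with the compounds were not tested.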

How the results depend on the processing

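Alternatives fixed before the data were examined are given first, and the 4 added after the data were seen are said to be so. The lists named next kept their direction over 9 settings. Against matched lists, mitosis and cytokinesis lay between -3.21 and -2.47 with IPTG alone, lysosome between 0.70 and 0.78, extracellular matrix between 0.38 and 0.75, and TGF-beta and SMAD targets with Senexin A alone between 0.38 and 0.53. Of the list values, 946 stayed within the interval of the list's median, or within the range of the members for lists with under 6 counted genes, and 23 moved beyond it. A change of sign was seen in 61 of 970, each in a list whose excess was 0.32 or less in size, and 60 of these lists had lain within the central 95% of matched lists. The other was mitosis and cytokinesis with Senexin A alone under the stricter floor. Counts and retained shares moved more often, with 114 moved by over 1.5 times or beyond their interval and 66 not. Of named genes past 2-fold and CDKN1A, 1429 values stayed within the spread between probes of a gene and 168 did not, 134 of these in the authors' table, and 0 changed sign. Taking the mean of a gene's probes moved 0 counts. Dim genes limit what can be seen, since a difference near the floor lies close to background. Settings that left fewer than 3 counted members gave no list value. No paired analysis was possible because each group had 1 array and the arrays carry no replicate numbers. The cause was not tested for any value below, except that a smaller or larger size of change, or a stricter floor, changes counts by construction.

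Counts are of genes past 2-fold unless another size is given, each ratio is the median ratio of log2 effects, and each excess is that over matched lists. With no floor, the counts were 114 higher for IPTG alone and 38 higher and 46 lower for Senexin A alone. They were also 21 lower for Senexin A with IPTG present and 109 lower for the interaction. The retained share was 38.6% with a ratio of 0.51 for genes that rose. For the DNA repair and chromatin list the excess was 0.35 for the interaction. For the extracellular matrix list the excess was 0.38 for IPTG alone and 0.31 for IPTG with Senexin A present. For the AhR targets list the excess was 0.00107 for Senexin A alone. For the endothelial markers list the excess was 0.10 for IPTG alone. After quantile normalization, the counts were 295 higher and 650 lower for IPTG alone, 4 lower for Senexin A alone and 42 higher for Senexin A with IPTG present. Further counts were 214 higher and 374 lower for the combined treatment and 195 higher and 54 lower for the interaction. Its retained share was 33.2% with a ratio of 0.61 for genes that rose and 39.4% with a ratio of 0.56 for genes that fell. For the endothelial markers list the excess was -0.11 for IPTG with Senexin A present. CDKN1A stood at 1.02 for IPTG alone. After cyclic loess, the counts were 216 higher and 767 lower for IPTG alone and 38 higher for Senexin A with IPTG present. Beside these were 462 lower for the combined treatment and 262 higher and 35 lower for the interaction. Here the retained share was 39.4% with a ratio of 0.70 for genes that rose and 36.5% with a ratio of 0.53 for genes that fell. For the endothelial markers list the excess was -0.10 for IPTG with Senexin A present. CDKN1A stood at 0.98 for IPTG alone. With the reference genes centred, the counts were 164 higher and 863 lower for IPTG alone and 10 higher and 10 lower for Senexin A alone. They were also 217 higher and 390 lower for the combined treatment and 351 higher and 22 lower for the interaction. The retained share was 51.8% with a ratio of 0.87 for genes that rose and 29.5% with a ratio of 0.46 for genes that fell. In the authors' table, the counts were 678 higher and 647 lower for IPTG alone, 10 higher and 5 lower for Senexin A alone and 73 higher for IPTG with Senexin A present. Further counts were 7 higher and 7 lower for Senexin A with IPTG present and 28 higher and 447 lower for the interaction. Its retained share was 8.41% with a ratio of 0.11 for genes that rose and 46.7% with a ratio of 0.73 for genes that fell. For the mitosis and cytokinesis list the excess was -2.24 for IPTG with Senexin A present and 0.15 for Senexin A with IPTG present. For the extracellular matrix list the excess was 0.48 for Senexin A alone. For the AhR targets list the excess was 0.27 for Senexin A alone, -0.29 for Senexin A with IPTG present and -0.58 for the interaction. For the epithelial markers list the excess was -0.70 for the interaction.

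At a size of 1.5-fold, the counts were 343 higher and 3291 lower for IPTG alone, 37 higher and 446 lower for Senexin A alone and 392 higher and 976 lower for IPTG with Senexin A present. Beside these were 617 higher and 22 lower for Senexin A with IPTG present, 384 higher and 2105 lower for the combined treatment and 2236 higher and 117 lower for the interaction. Here the retained share was 42.3% with a ratio of 0.62 for genes that rose and 28.7% with a ratio of 0.39 for genes that fell. At a size of 3-fold, the counts were 11 higher and 434 lower for IPTG alone, 0 higher and 0 lower for Senexin A alone and 17 higher and 156 lower for IPTG with Senexin A present. They were also 5 higher and 0 lower for Senexin A with IPTG present, 29 higher and 231 lower for the combined treatment and 35 higher and 0 lower for the interaction. The retained share was 35.5% with a ratio of 0.62 for genes that fell. With the floor at the pooled 75th percentile, the counts were 1028 lower for IPTG alone, 9 lower for Senexin A alone and 74 higher for IPTG with Senexin A present. Further counts were 1 lower for Senexin A with IPTG present, 446 lower for the combined treatment and 340 higher and 5 lower for the interaction. Its retained share was 83.3% for genes that rose. For the mitosis and cytokinesis list the excess was -2.47 for IPTG alone, 0.0325 for Senexin A alone, -2.27 for IPTG with Senexin A present and 0.16 for Senexin A with IPTG present. For the DNA replication list the excess was 0.10 for Senexin A alone. For the DNA repair and chromatin list the excess was -1.41 for IPTG alone, -1.39 for IPTG with Senexin A present and -0.10 for the interaction. With a floor on the mean, the counts were 12 lower for Senexin A alone. Here the retained share was 18.6% for genes that fell. For the DNA repair and chromatin list the excess was -0.29 for Senexin A alone and 0.35 for the interaction. With the selecting comparison exchanged, the retained share was 35.1% with a ratio of 0.65 for genes that rose and 98.2% with a ratio of 1.33 for genes that fell.

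Added after the data were seen were the following. With the median of the counted genes removed, the retained share was 29.6% with a ratio of 0.53 for genes that rose and 42.8% with a ratio of 0.62 for genes that fell. In the authors' table with the median removed, the retained share was 11.5% with a ratio of 0.24 for genes that rose and 44.1% with a ratio of 0.65 for genes that fell. After cyclic loess with the median removed, the retained share was 37.0% with a ratio of 0.69 for genes that rose and 37.1% with a ratio of 0.54 for genes that fell. In the authors' table with the brightness trend removed, the retained share was 34.6% with a ratio of 0.67 for genes that rose and 33.1% with a ratio of 0.49 for genes that fell.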

Other observations

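Few genes responded to Senexin A alike without and with IPTG. With the medians of all counted genes removed, 20 genes were at least 1.5-fold higher in both Senexin A effects, where independent lists would share 2.68, and 5 were lower in both, where independent lists would share 1.93. The 20, named after their values were seen, were AMIGO2, CCN2, COL4A1, EDN1, ESM1, F2R, FRMD6, GALNT4, HHIP, INHBA, ITGB3, KLHDC8B, LINC00472, MMP7, NUPR1, SLC14A1, STK38L, TGFB2, THBS1 and YPEL2. Without IPTG, KLHDC8B and MMP7 lay under the floor in both arrays. Another 21 genes were at least 1.5-fold apart in opposite directions, where independent lists would give 6.28, and across all counted genes the Senexin A effects without and with IPTG had an r of -0.32 and a rho of -0.40.

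Of the serum and immediate early genes, 6 of 19 fell with IPTG alone, and the list lay within the range of matched lists (percentile 20.3). Picked from these 6 after their values were seen, DUSP1, DUSP5, SPRY2 and SPRY4 had log2 differences of -1.06, -1.19, -1.15 and -1.18 with IPTG alone, and of -0.02, -0.11, -0.05 and 0.03 with IPTG in the presence of Senexin A. In the authors' table they stood at -0.76, -1.19, -0.78 and -1.06, and at -0.13, -0.33, -0.21 and -0.17. MYC and JUN, also among the 6, stood there at -1.49 and -1.10 with IPTG alone, and at -0.64 and -0.66 with Senexin A present. The median interaction of all counted genes was 0.30 in the deposited intensities. Added to IPTG, Senexin A gave a difference of 1.06 for DUSP1 and 1.04 for MYC, and of 0.70 and 0.51 in the authors' table. Their list lay at percentile 92.7 of matched lists in that comparison and at 70.4 in the interaction.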
